A study of Mus musculus with 6 samples.

How the data were processed

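Total RNA from 6 mouse CD4+CD25+ T cell samples was labelled with biotin and hybridised to Affymetrix Mouse430a arrays, 3 wild type and 3 Hdac3 deleted. Per the labels, the authors normalised the arrays by robust multiarray average (RMA) with MAYDAY 2.12 and tested them with Student's test, and the deposited values are log2 expression per probe set. RMA sets the arrays to a common distribution, so a change in the total RNA of a cell cannot be seen, and a large one-sided change in many genes shifts the others. Signal at the low end is background: 27 bacterial (Bacillus subtilis) control probe sets spanned 2.37 to 5.16 log2 over the 6 samples. Where 1 group of a gene lay in that range and the other above it, the fold is given as "at least", measured from the top of the range. The number of arrays limits the precision, and 3 per group is small.

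The table held 22690 probe sets. The 64 Affymetrix control probe sets were left out, leaving 22626. By the platform annotation 20380 probe sets had 1 gene symbol, 691 had several and 1555 had none. Of those with 1 symbol, 20351 matched the RefSeq gene table (GRCm38.p6) by Entrez identifier, no symbol changed, and 29 kept the platform symbol. A gene was represented by the probe set with the highest mean over all 6 samples among those with 1 symbol, giving 12393 genes, 4956 of which had more than 1 probe set.

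Groups came from sample titles. Differences were tested two-sided with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all probe sets or all genes, in place of the authors' test. The threshold was adjusted p 0.05 with at least a 2-fold difference, as the authors used. Of 32 gene lists fixed before the data were examined, 31 had at least 5 measured genes and were tested with camera, with its preset correlation of 0.01 between genes and adjustment over the lists. Annotation and plots used Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. Members of a list are counted as risen or fallen by the adjusted p over all genes, with the count over the list alone beside it where it is given.

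Named genes followed a rule fixed beforehand. They are Hdac3, Hdac11 and Foxp3; the 10 largest rises and the 10 largest falls in genes past both thresholds whose groups did not overlap; up to 4 members per list with the smallest p; and any member of the T helper cytokine, regulatory T cell signature, and deacetylase and corepressor lists. Others are said to be chosen after the values were seen.

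Tests were checked on simulated data made from the real means and spreads of this comparison, over 12393 genes. The limma fit recovered 60%, 94%, 100% and 100% of genes changed by 0.5, 1, 2 and 4 log2, with 7 false calls among 12164 unchanged genes. The list test recovered the raised cell cycle list and called 0 of the other lists. Genes were drawn independently there and few were changed, so this cannot show how the list test behaves on genes that move together.

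Alternatives were the methods' test, replicate number as a block, quantile normalization again, median centring, cyclic loess, leaving out the dimmest 33.3% of probe sets, a trended robust prior, array weights, leaving out each sample, a 1.5-fold threshold, leaving out probe sets that can match several transcripts, the mean of a gene's probe sets, camera with an estimated correlation and fry. Values relative to the 4 CD3 genes were added after the macrophage rise was seen, for all counts, named genes and lists. All 3 Hdac3 deleted samples carry that rise, so no sample could be left out on its account.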

Results

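Gene expression was measured in mouse CD4+CD25+ T cells, a surface phenotype that enriches for regulatory T cells, with 1 Affymetrix Mouse430a array per sample. The 6 samples comprised 3 from wild type mice and 3 from mice with a floxed Hdac3 gene and a Cre recombinase named for Foxp3, called Hdac3 deleted here. Hdac3 is a histone deacetylase and Foxp3 is the lineage factor of regulatory T cells. The question was how loss of Hdac3 changes gene expression in these cells. Nothing in the labels says that samples came from separate animals, so p-values measure only the spread between these samples, which may be technical. Sample medians were 6.28 to 6.29 (log2) in wild type and 6.43 to 6.47 in Hdac3 deleted samples. Pearson correlation across probe sets was 0.996 to 0.997 within wild type, 0.997 to 0.998 within Hdac3 deleted samples, and 0.921 to 0.923 between groups. The first principal component held 94.7% of the variance. Log2 values are given as mean ± SD with n = 3 per group, and a difference is Hdac3 deleted minus wild type.

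The targeted gene was lower on the deposited scale but not lost. Hdac3 measured 9.07, 9.04 and 9.01 in the wild type samples and 8.46, 8.51 and 8.50 in the Hdac3 deleted samples. Its mean went from 9.04 ± 0.028 to 8.49 ± 0.024, a difference of -0.55 (SE 0.050, limma adjusted p = 7.45e-05), and it was -0.37 with cyclic loess and -0.71 with median centring. The CD3 genes of T cells fell by more (1.47), and relative to them, a scale chosen after the data were seen, Hdac3 was higher by 0.91 (adjusted p = 2.63e-06). On that scale 97.7% of all genes were higher, with a median of 1.30 over all genes, which lies above the value of Hdac3. Whether its 1 probe set lies in the deleted exons is not known here, so the value is at most a weak check of the labels. A difference as low or lower was seen in 15.0% of all genes. One label field of the Hdac3 deleted samples names a different deacetylase, Hdac11, and another gives a form that could be read in more than 1 way, against the title and genotype, which name Hdac3. Hdac11 measured 5.41, 5.54 and 5.46 in wild type and 4.88, 4.74 and 5.04 in Hdac3 deleted samples, at least 1.24-fold lower (adjusted p = 0.000864), since the Hdac3 deleted mean lay inside the background range of 2.37 to 5.16. Foxp3 lay inside that range in both groups, at 3.77 ± 0.291 and 3.68 ± 0.153 (adjusted p = 0.652), so its level could not be read from this probe set.

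**Figure D1:**
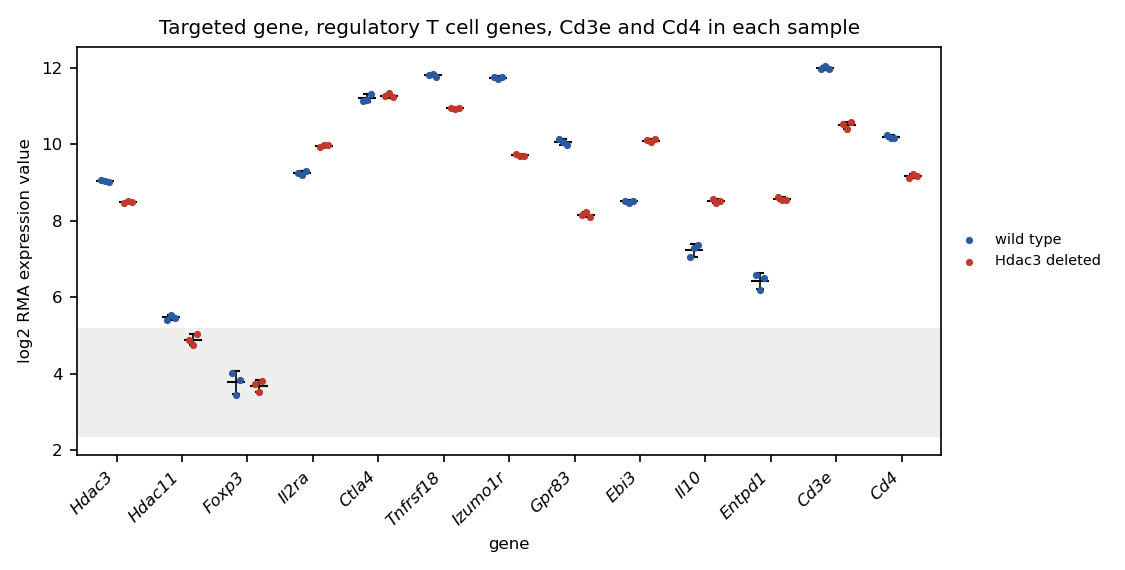
Log2 RMA expression of the targeted gene, regulatory T cell genes, Cd3e and Cd4 in each sample (points), with mean and SD (black), for 3 wild type and 3 Hdac3 deleted samples. The grey band spans the bacterial control probe sets, 2.37 to 5.16, and holds Foxp3 in both groups.

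Genes of macrophages and neutrophils were far higher in the Hdac3 deleted samples. All 22 measured monocyte and macrophage markers rose, with a median difference of 6.83, or 6.34 with background levels set at the top of the background range, and each at least 2-fold higher (camera adjusted p = 2.65e-20). Csf1r, the receptor for the macrophage growth factor, rose from 6.66 ± 0.070 to 14.2 ± 0.019, and the complement gene C1qb rose from 5.14 ± 0.090 to 13.8 ± 0.060, at least 398-fold. All 15 neutrophil markers rose, with a median of 5.28, or 4.75 on those bounds (adjusted p = 7.18e-14), among them S100a8, at least 246-fold higher at 13.1 ± 0.040, and the granule enzyme Mpo, at least 163-fold higher. Of 13 dendritic cell markers 6 rose and none fell, among them Batf3, at least 36.7-fold higher, and Itgax, up by 4.29 (camera adjusted p = 0.000322, adjusted p = 0.0607 with an estimated correlation). The 4 genes grouped here as MHC class II are H2-Aa, H2-Ab1, H2-Eb1 and Cd74, which encodes the associated invariant chain. H2-Aa, H2-Eb1 and Cd74 rose by 8.49, 7.78 and 5.60 and H2-Ab1 at least 308-fold. They belong to the B cell list, of whose 18 measured members 10 rose and 2 fell (adjusted p = 0.000636, adjusted p = 0.0878 with an estimated correlation). Of the other 14 members 6 rose, 3 of them at least 2-fold, and 2 fell. Cd79a, chosen after the values were seen like Ms4a1 and Pax5, differed by -0.26 (adjusted p = 0.0716). It lay just above the background range, at 5.48 in wild type and 5.21 in Hdac3 deleted samples, so its direction is barely resolved. Cd79a was called lower without wild type replicate 1 (-0.37, adjusted p = 0.0107), with median centring (-0.42, 0.0116), with array weights (-0.30, 0.0293) and with the replicate number as a block (adjusted p = 0.0486). Ms4a1 and Pax5 lay inside the background range in both groups, at 4.64 and 4.33 and at 4.60 and 4.64 (adjusted p = 0.115 and 0.650), so calls of Ms4a1 without wild type replicate 2 (-0.45, adjusted p = 0.0217) and with median centring (-0.46, 0.0233) and of Pax5 with cyclic loess (0.22, 0.0287) give no readable direction.

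T cell genes moved the other way in the same samples. The 4 CD3 genes Cd3d, Cd3e, Cd3g and Cd247 averaged 12.22 ± 0.043 in wild type and 10.75 ± 0.017 in Hdac3 deleted samples and fell by 1.47. Of 19 measured T cell receptor signalling components 16 fell and 1 rose, also when adjusted over the list alone, with a median of -0.76 (camera adjusted p = 0.000431, adjusted p = 0.138 with an estimated correlation). Prkcq fell by 1.54, Lat by 1.53 and Cd247 by 1.59. Of 16 naive and central T cell genes 13 fell and 1 rose, with a median of -1.01 (adjusted p = 0.000636, adjusted p = 0.0855 with an estimated correlation). The transcription regulators Id3 and Bach2 fell by 3.16 and 2.05, and S1pr1, which guides exit from lymph nodes, fell by 1.55. Cd4, chosen after the values were seen, fell by 1.02. Of 16 thymocyte genes 9 fell and 2 rose (adjusted p = 0.274), with Bcl11b down by 1.46 and Tox by 2.44.

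**Figure D2:**
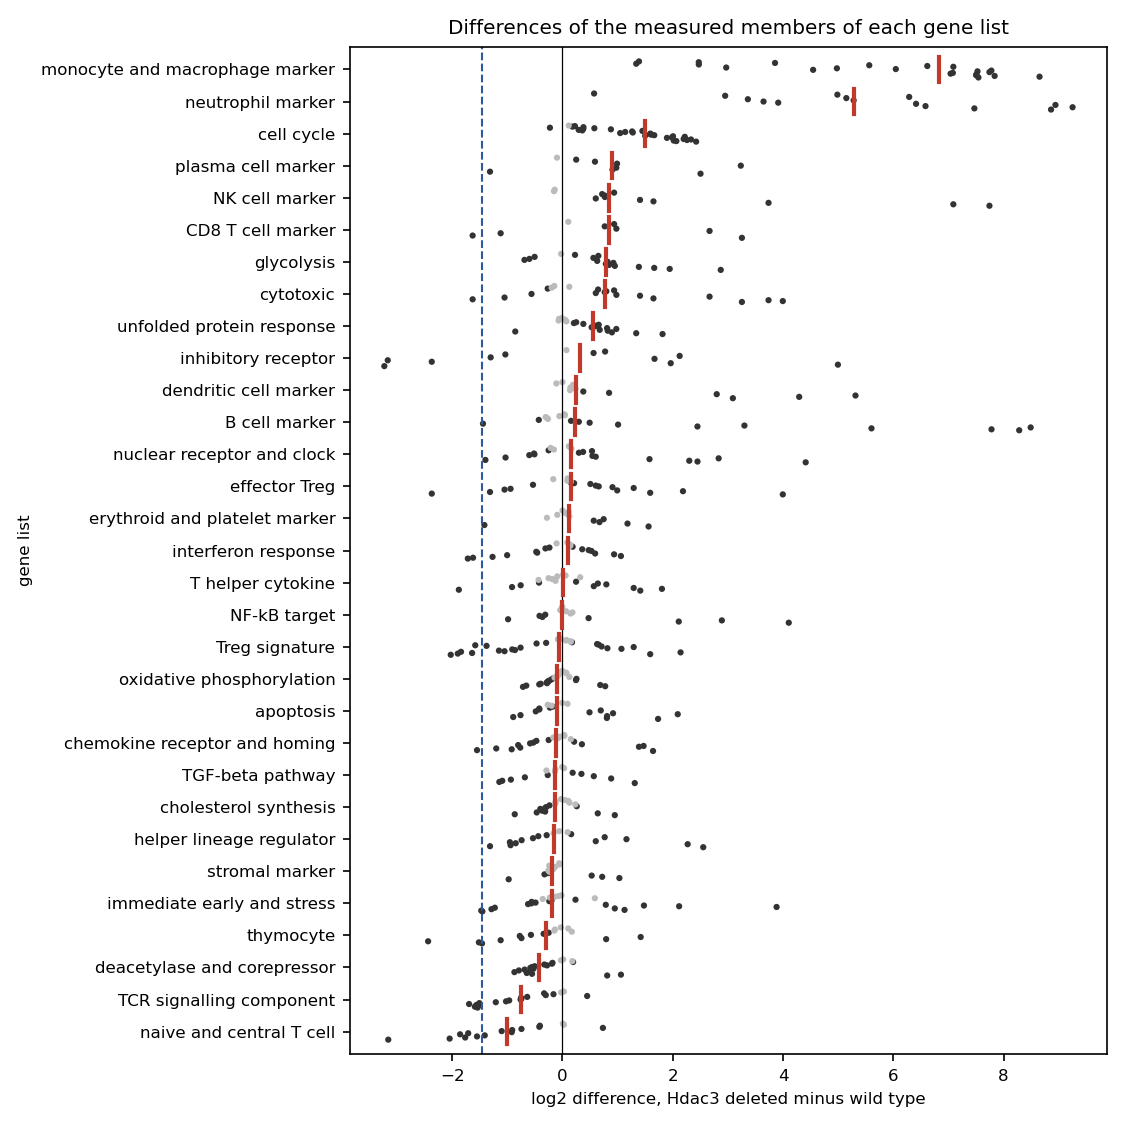
Log2 difference (Hdac3 deleted minus wild type) of each measured member of the 31 tested gene lists, dark points past adjusted p 0.05 and pale points not, with the list median as a red bar and the CD3 gene mean of -1.47 as a dashed line. Macrophage and neutrophil markers stand furthest right, with medians of 6.83 and 5.28.

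Genes of the regulatory T cell signature changed in both directions while the CD3 genes fell by 1.47 and macrophage markers rose. Of 28 measured members 9 rose, 13 fell and 6 did not pass (camera adjusted p = 0.973), and 10 rose and 13 fell when adjusted over the list alone. Il2ra, which encodes CD25, was 9.25 ± 0.047 and 9.96 ± 0.022, higher by 0.71 (adjusted p = 2.67e-05). Ctla4, an inhibitory receptor, differed by 0.07 (adjusted p = 0.401), and by 0.29 with cyclic loess (adjusted p = 0.00801). The ectonucleotidase gene Entpd1, the cytokine subunit gene Ebi3 and the cytokine gene Il10 rose by 2.14, 1.59 and 1.29. Izumo1r, Gpr83, Penk, Ikzf2, Tnfrsf18 and Ikzf4 fell by 2.03, 1.90, 1.64, 1.58, 0.86 and 0.76. Relative to the CD3 genes 22 of the 28 members were higher and 3 lower, on a scale where 97.7% of all genes were higher, with Tnfrsf18 and Ikzf4 at 0.61 and 0.71, Izumo1r and Gpr83 at -0.56 and -0.43, and Penk and Ikzf2 not past the threshold (adjusted p = 0.0601 and 0.353). Of 21 effector regulatory T cell genes 11 rose and 5 fell (adjusted p = 0.0148, adjusted p = 0.219 with an estimated correlation, 0.0514 with cyclic loess and 0.0553 without the dimmest probe sets). The granule protease Gzmb rose from 7.95 ± 0.129 to 11.9 ± 0.036, while Pdcd1 and Irf4 fell by 2.37 and 1.31.

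Of 19 T helper cytokine genes 7 rose, 4 fell and 8 did not pass (camera adjusted p = 0.296). Among those that rose, Il6 (3.04 and 3.68) and Il3 (3.50 and 3.75) lay inside the background range in both groups and give no readable direction. Csf2 was at least 2.58-fold higher, Lta rose by 1.41 and Ifng by 0.80, and Tnfsf11 fell by 1.88. Il4 lay near background, at 5.33 in wild type, and Il17a inside the background range in both groups, at 5.09 and 5.14. They differed by 0.01 and 0.06 (adjusted p = 0.927 and 0.746). Il2, inside the background range at 4.44 and 4.02, differed by -0.43 (adjusted p = 0.0117, and 0.0505 with the methods' test). Of 19 cytotoxic genes 12 rose and 4 fell (adjusted p = 0.00189, adjusted p = 0.0811 with an estimated correlation), with Gzma up by 3.74 and Ccl5 up by 3.25 but Ctsw down by 1.63. Of 12 natural killer cell markers 10 rose (adjusted p = 1.47e-05), among them Tyrobp, at least 206-fold higher, and Fcer1g (7.09), which the macrophage list also holds. The inhibitory receptor list was split, with 6 up and 5 down of 12 (adjusted p = 0.386), with Cd244a at least 9.52-fold higher, Cd274 up by 1.96 and Cd96 down by 3.23. A second Cd244a probe set was at least 1.93-fold higher. In the same samples macrophage markers were higher by a median of 6.83.

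Cell cycle genes were higher. Of 31 members 29 rose and 1 fell, also when adjusted over the list alone, with a median of 1.5, or 1.45 on those bounds (camera adjusted p = 5.36e-14), among them the proliferation marker Mki67 (2.42), Top2a (2.26), Birc5 (2.07) and Aurka (2.02). Glycolysis genes rose in 13 and fell in 3 of 17 members (median 0.79, adjusted p = 5.59e-05), with hexokinase Hk2 up by 2.87 and Tpi1 by 1.94. Unfolded protein response genes rose in 14 and fell in 1 of 20 (median 0.55, adjusted p = 5.41e-05), Atf6 by 1.81 and Sdf2l1 by 1.34, while Ddit3 fell by 0.86. Of 20 deacetylase and corepressor genes 14 fell and 3 rose (median -0.42, or -0.32 on those bounds, adjusted p = 0.223), Hdac1 falling by 0.65 while Sirt3 rose by 1.06. Of the 14 calls made by camera, 6 held with an estimated correlation, most of them close to the threshold. They were the macrophage list (adjusted p = 0.014) and the neutrophil, natural killer, cell cycle, glycolysis and unfolded protein response lists (0.047 each). The macrophage rise and the CD3 fall accompanied each of them.

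Nuclear receptor and clock genes rose in 10 and fell in 6 of 21 (adjusted p = 0.0303, adjusted p = 0.138 with an estimated correlation, 0.0814 with cyclic loess, 0.0748 with the mean of a gene's probe sets, 0.0741 with quantile normalization again and 0.0718 without the dimmest probe sets), with Pparg at least 12.2-fold higher and a Dbp difference of -1.40. Plasma cell markers rose in 7 and fell in 1 of 9 (adjusted p = 0.00754, adjusted p = 0.103 with an estimated correlation), Jchain by 2.50. The camera test gave no call for helper lineage regulators (6 rose and 8 fell of 17, adjusted p = 0.973; Id2 up by 2.55, Gata3 down by 0.94), chemokine receptors and homing genes (5 and 9 of 20, 0.974), immediate early and stress genes (7 and 10 of 23, 0.989) and NF-kB targets (4 and 4 of 15, 0.181). Nor did it for interferon response genes (7 and 8 of 20, adjusted p = 0.660), where Ifit1 and Usp18 fell by 1.72 and 1.62 and Gbp2 rose by 1.06. The remaining lists were oxidative phosphorylation (4 rose and 11 fell of 27, adjusted p = 0.715), cholesterol synthesis (3 and 9 of 19, 0.973), apoptosis (7 and 7 of 18, 0.386) and TGF-beta pathway (5 and 5 of 15, 0.943). Also without a call were CD8 T cell markers (5 and 2 of 8, adjusted p = 0.0719, but called with median centring at 0.0229, with the mean of a gene's probe sets at 0.0449 and with the replicate number as a block at 0.0491), erythroid and platelet markers (5 and 1 of 12, 0.0941) and stromal markers (3 and 3 of 14, 0.943). Adjusted over the list alone, the numbers that rose and fell were 12 and 5 for effector regulatory T cell genes, 12 and 5 for cytotoxic genes, 4 and 14 for deacetylases and corepressors, 6 and 9 for helper lineage regulators, 6 and 9 for chemokine receptors, 8 and 12 for immediate early genes, 8 and 8 for interferon response, 7 and 8 for apoptosis and 3 and 2 for stromal markers. In the other lists, apart from the regulatory T cell signature, they equalled those over all genes. The median and the direction of the camera test differed in sign in 7 lists and the mean and that direction in 4, and camera called 0 of the 7.

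By measured difference the 10 largest rises were in S100a8, S100a9, Cxcl9, Chil3, C1qb, Mgst1, H2-Aa, Fcgr4, Pla2g7 and H2-Ab1. All but H2-Aa lay in the background range in wild type, so these genes have no order among themselves. Besides those already given, Fcgr4 was at least 241-fold higher, S100a9 at least 238-fold, Cxcl9 at least 222-fold, Pla2g7 at least 143-fold, Chil3 at least 139-fold and Mgst1 at least 130-fold. By the same rule the 10 largest falls included Trim34a (-4.22), Ncmap (-3.34), Itm2a (-3.29), Cd96 (-3.23) and Cd200 (-3.17), measured above background in both groups. The others reached the background range in Hdac3 deleted samples, with Trim12a at least 16.7-fold lower, Fgf13 at least 11.5-fold, Gsta4 at least 9.87-fold, Mcoln3 at least 3.67-fold and Gt(ROSA)26Sor as given next. A second Trim34a probe set went the other way, by 0.46 (adjusted p = 0.0377). A second Trim12a probe set was at least 1.36-fold lower, and second probe sets of Fgf13, Mcoln3 and Mgst1 lay inside the background range in both groups, with Mgst1 at 3.16 and 3.07 where its first set reached 12.2. Gt(ROSA)26Sor, a transcript of a locus widely used for transgenes, went from 8.78 ± 0.175 to 3.67 ± 0.226, at least 12.3-fold lower.

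**Figure D3:**
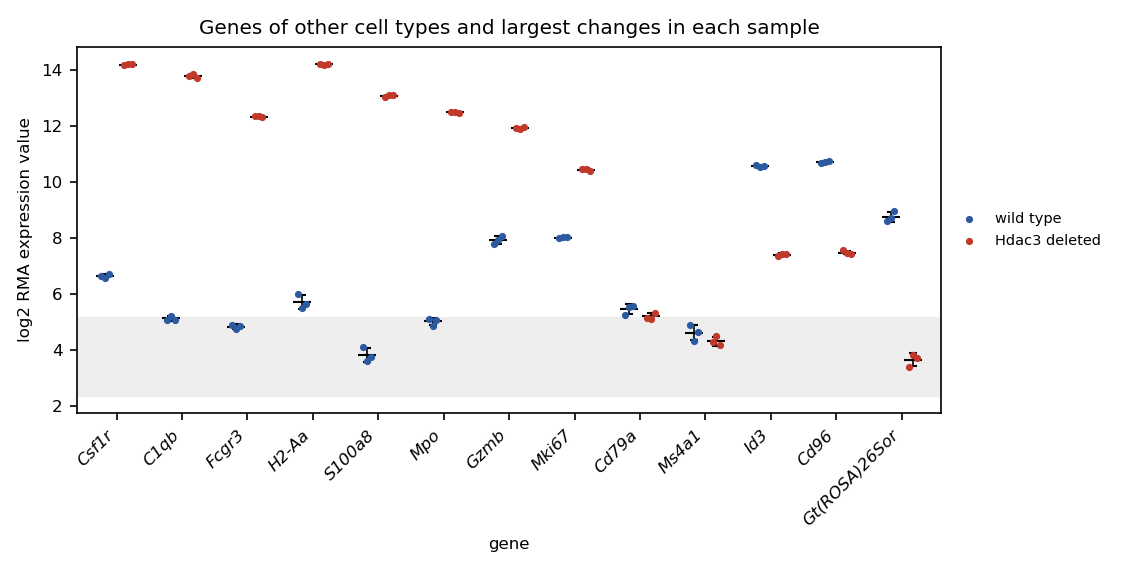
Log2 RMA expression of macrophage, neutrophil, B cell and other genes in each sample (points), with mean and SD (black), for 3 wild type and 3 Hdac3 deleted samples; the grey band spans the bacterial control probe sets. Csf1r went from 6.66 to 14.2, whereas Cd79a and Ms4a1 were at 5.21 and 4.33 in Hdac3 deleted samples.

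In total 2769 of 22626 probe sets passed adjusted p 0.05 and a 2-fold difference, 1790 higher and 979 lower in Hdac3 deleted samples. With 1 probe set per gene, 1673 of 12393 genes passed, 1120 higher and 553 lower, so 66.9% were higher, against 53.2% with median centring and 79.1% with cyclic loess. With no fold threshold 13032 probe sets passed, 4559 higher and 8473 lower, so 35.0% were higher, against 21.7% with median centring and 55.7% with cyclic loess. For probe sets past 2-fold the shares were 64.6%, 50.7% and 77.8%. The median difference over genes was -0.17, and it was -0.33 with median centring and 0.00 with cyclic loess, so small differences have no settled direction. With background levels set at the top of the background range, 162 genes were at least 16-fold higher and 2 at least 16-fold lower. The 3 values per group did not overlap in 8352 genes (67.4%), where chance gives 10%.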

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

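The tests in this part were chosen after the results were seen. Control probe sets outside the comparison differed both ways. The Gapdh control probe sets were higher by 0.84, 0.68 and 0.81 (3', 5' and middle), and the 3' transferrin receptor set was higher by 0.68 although it lay inside the background range, while the middle 18S ribosomal set was lower by 1.10 and 1 other murine control set lower by 0.66.

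The macrophage and neutrophil rise is the pattern a reader would want to follow first. Myeloid cells or their RNA in the Hdac3 deleted preparations may be the source. In these samples 36 of 37 measured macrophage and neutrophil markers (97.3%) were at least 2-fold higher, with Csf1r at 14.2 and C1qb at 13.8. The CD3 genes were lower. These values are the pattern itself, already seen, and so are no separate test of this source. In wild type 13 of the 22 macrophage and 4 of the 15 neutrophil markers were above background, other lists hold 3 of the macrophage markers, and a CD4+CD25+ gate would be meant to remove these cells. B cells are argued against as the source of the MHC class II rise, since the other 14 B cell markers had a median of 0.039 (SD 1.21), and the 7 of them above background in a group one of 0.49 (SD 1.24), beside a smallest rise of 5.60 in the 4 MHC class II genes. Expression of these genes by the T cells themselves, after Hdac3 loss, cannot be told apart from added cells with pooled RNA, and the CD3 difference of -1.47 does not decide it.

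T cell genes fell by different amounts, for example Cd4 by 1.02, Cd3d by 1.21, Id3 by 3.16 and Cd96 by 3.23. As far as the CD3 genes measure it, a lower share of T cells as the whole cause is argued against for 18 genes. They fell at least 2-fold further than the CD3 genes past adjusted p 0.05, with background levels set at the top of the background range. They were picked from all genes and not from T cell genes alone, and include Trim34a, Trim12a and Gt(ROSA)26Sor beside Id3 and Cd96. A second Trim34a probe set rose by 0.46 and a second Trim12a set was at least 1.36-fold lower. The place of Trim34a and Trim12a among the 18 thus depends on the probe set used. Compressed signal of the bright CD3 probe sets is argued against too, since 12 genes, on the same bounds, fell at least 2-fold further than Cd28, which fell by 1.69. A change within the T cells from Hdac3 loss, or a different mixture of T cell subsets, stays open and was not tested. Other causes for single genes were not tested either.

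The loss of Gt(ROSA)26Sor signal exceeded what a lower share of T cells gives, as far as the CD3 genes measure it. It was -2.15 or lower relative to the CD3 genes, with its Hdac3 deleted level set at the top of the background range. An allele difference that lowers the 10 nearest measured genes together is argued against. Their median difference was -0.24 (SD 0.84), near the median of all genes of -0.17. Single neighbours differed both ways, such as Thumpd3 by -0.53, Tada3 by -0.72 and Camk1 by 2.12, so a smaller or narrower effect is not decided. A change of the Gt(ROSA)26Sor locus alone, such as an inserted transgene, was not tested and stays open, as does an effect of Hdac3 loss.

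The 3 wild type and 3 Hdac3 deleted samples make 10 splits, too few for a share under 0.05. The real one gave 2769, 13032 and 1673 for the 3 gene and probe set counts and the highest other gave 0, and for called lists it gave 14 and the highest other 13. In each case 1 split, the real one, was as large. The other splits still called 7 to 13 lists although they called 0 genes and probe sets. The number of called lists thus hardly separates the real grouping from the others.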

How the results depend on the processing

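The values relative to the CD3 genes were chosen after the results were seen, and the other alternatives were fixed before the data were examined. Probe sets past both thresholds were 2735 to 2823 over the samples left out in turn, probe sets past adjusted p 11451 to 12261, genes past both thresholds 1659 to 1714, the Hdac3 difference -0.57 to -0.54, and called lists 14 in each. A 1.5-fold threshold gave 5841 probe sets by its own construction, and leaving out the probe sets that can match several transcripts gave 1816, since fewer were tested. Camera with an estimated correlation called 6 lists and fry 30. The fry test asks whether a list moves one way and does not compare it with other genes. Relative to the CD3 genes, which fell by more than most genes, 18298 probe sets passed both thresholds, 22308 adjusted p alone and 10028 genes both thresholds (23 lower), by the scale's own construction. Hdac3 turned to 0.91 there, and the direction also turned for Hdac11 (0.88), Foxp3 (1.38), Ikzf4 (0.71), Tnfrsf18 (0.61), Irf4 (0.15), Cd3d (0.26), Cd4 (0.44), Il2 (1.04), Gata3 (0.52), Hdac1 (0.82), Ddit3 (0.61), Cd79a (1.20), Ms4a1 (1.16), Kdm5d (0.45), Eif2s3y (1.28) and Xist (1.37). There 11 named genes lost their call, including Dbp (0.069) and Bcl11b (0.0075), whose sign changed. Camera called 12 lists on that scale, 7 up and 5 down. The regulatory T cell signature (median 1.41) and inhibitory receptors (1.79) turned from up without a call to a call down. Oxidative phosphorylation (1.38) turned from down without a call to a call up. The median over all genes was 1.30 there, so these list medians do not show the direction of the call. Of the other lists 6 lost a call and 1 gained one. Since 1 reference is subtracted from all genes, differences between genes stay as they were, and these changes of calls show no change against other genes. Under fry the direction turned, past its threshold, for the regulatory T cell signature (median -0.055), helper lineage regulators (-0.16), inhibitory receptors (0.32), immediate early and stress genes (-0.20), interferon response (0.11) and TGF-beta pathway (-0.13), none of which camera had called. With the replicate number as a block, 2769 probe sets passed both thresholds, 12534 adjusted p alone and 15 lists were called, the added list being CD8 T cell markers (adjusted p = 0.0491). Same-numbered samples correlated by 0.0924, 0.0839 and -0.189 in their deviations, so the numbers do not pair the samples, and of the named genes and lists the block otherwise changed only Cd79a. The methods' test gave 2764 probe sets past both thresholds and 11235 past adjusted p. Of the named genes' values under the alternatives fixed beforehand none reversed, 1425 kept direction and side of the threshold, 1 (Il2, with the methods' test) lost its call and 11 gained one. Of the list values under those alternatives 493 kept theirs, 14 lost a call and 13 gained one. There, besides the estimated correlation, only the effector regulatory T cell list and the nuclear receptor and clock list lost a call. Levels near background, as for Foxp3, Il2, Il4 and Il17a, are barely resolved.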

Other observations

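The gene groups below were put together after the values were seen. Elane belongs to the fixed neutrophil list and Cxcl9 to the 10 largest rises. Eif2s3y, Kdm5d and Xist belong to a fixed sex linked list, which had fewer than 5 measured genes and was not tested. The other genes below come from no fixed list. Some genes known from red pulp macrophages of the spleen were high in the Hdac3 deleted samples: Cd5l rose from 5.65 to 13.6, Vcam1 from 6.49 to 13.9, the iron exporter Slc40a1 from 6.85 to 13.3 and the transcription factor Spic from 5.26 to 11.5. Some granule genes of immature neutrophils were also high, with Prtn3 rising from 5.32 to 12.4, Ctsg from 4.72 to 11.8 (at least 97.2-fold) and Elane from 5.61 to 10.9. No wider set of either kind was tested. Cxcl9 and Ubd were at least 222-fold and at least 96.4-fold higher.

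The Y-linked genes Eif2s3y and Kdm5d were expressed in all samples, Eif2s3y at 9.45 and 9.26 in the 2 groups and Kdm5d at 7.82 and 6.81, lower by 1.01 (adjusted p = 3.93e-05), and Xist was at 4.43 and 4.34, inside the background range. The 18S ribosomal control probe set at the 5' end was lower by 2.01 in Hdac3 deleted samples (adjusted p = 0.000491), at 11.2 and 9.19. The 3' minus 5' difference of the Gapdh control was 0.196 to 0.509 in wild type and 0.484 to 0.524 in Hdac3 deleted samples.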
